A study of Rattus norvegicus with 5 samples.

How the data were processed

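Anti-PARP1 chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out on the central amygdala of male Sprague Dawley rats. PARP1 is poly(ADP-ribose) polymerase 1, a nuclear enzyme that attaches ADP-ribose chains to proteins and takes part in DNA repair and in the control of transcription. Per the labels, rats went through 10 days of cocaine conditioned place preference training, with 15 mg/kg cocaine given intraperitoneally on days that alternated with saline. Preference was tested for 15 min at 24 h after the last injection, and the tissue was taken straight after that test. Each library pooled the tissue of 2 rats. The labels gave 1 ChIP library from rats with a high preference for the cocaine compartment, 1 from rats with a low preference and 2 from rats that had received only saline. A further sample, input DNA from the low preference group, was not analysed here. Groups were taken from the group label of each sample.

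The submitters' processing notes name Bowtie 0.12.7, Picard 1.37 and the rat genome build rn4. The role of each tool, the peak caller, its settings and the treatment of duplicate reads are not given in the sources used here. Per the labels' protocols, the immunoprecipitated DNA was sheared again to about 150 bp and ChIP libraries went through 15 cycles of PCR. The deposited data were peak lists, 1 per library and not pooled, with 7 columns, of which the file headers name the first 5 (a running number, the chromosome, the start, the end and the position of the summit). The deposited column 6 held whole numbers and was read as a signal, the pileup height in overlapping reads at the summit, with no scaling to depth. The deposited column 7 held a value between 0 and 1 that was read as a p-value or share. It was set by the chromosome and the height alone, and none of the 989 combinations of chromosome and height had more than 1 value over the 4 lists. It therefore added nothing to the height for comparing libraries and was not used for any comparison. Both readings rest on the values and not on a header.

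No height under 2 was listed. Of 45 chromosomes or parts of them, 43 had a lowest listed height of 2 in all 4 libraries. On unplaced sequence (chromosome Un) the lowest listed height was 3 in the low preference library and in saline replicate 2, and 2 in the others. The mitochondrial sequence held a single listed peak in 3 libraries and 17 in saline replicate 1, and it was left out of all comparisons. The running number rose by more than 1 between neighbouring peaks, so that it also counted pileups that were not listed. Estimated depth was the sum of listed heights plus 1 for each unlisted number, on the assumption that an unlisted pileup held 1 read. The shortest listed peak spanned 49 bp from start to end. Coordinates are printed as in the deposited lists, whose counting from 0 or 1 was not stated.

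The test designs were fixed before the data were examined. The highest peaks of each library were those above the height that left at most 5000 peaks. Overlap of at least 1 bp was counted for each of the 6 pairs as the share of the shorter list, with a 95% Wilson interval, and compared with 100 random circular shifts of the longer list along each chromosome. The 4 lists of highest peaks were merged into 6839 regions, and each library's value was the tallest listed peak that overlapped a region. Heights were divided by a scale factor, the sum of listed heights relative to the mean of the 4 libraries. A region was called for a single library when its scaled height was at least 4 times the largest of the 3 others. It was called for a pair of libraries when the lower of the pair was at least 2 times the higher of the other pair. A leading library had to list a peak, and a height under 3 was set to 3 in every library. A listed height of 2 in a leading library thus also counted as 3. In saline replicate 1 this floor amounts to 12.4 scaled reads, so with all 4 libraries a call for the high preference library, the low preference library or saline replicate 2 needed at least 55, 67 or 66 reads. Of the 6839 regions, 52, 42 and 56 reached that height. With the others at the floor, the rule asked for at least 3 reads in saline replicate 1, which 1722 regions reached. Where that library had under 5 reads, another had reached its own minimum of 6 or 7. The 1722 regions therefore overstate the reach. Profiles were compared over 100 kb bins as log2 of 1 plus summed heights in parts of 1000000 of the library's total. For chromosomes, the share of summed heights was divided by the share of the length covered by a listed peak in any library.

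With 1 library per cocaine group and 2 saline libraries a test between groups would have rested on very few residual degrees of freedom. None was run, and fixed rules of size were used in its place. The spread between the 2 saline libraries was the only measure of variation within a group. Intervals of heights are exact Poisson intervals, and those of height ratios are exact conditional binomial intervals. They cover counting error only, since PCR reads without molecular identifiers are not independent molecules. The size rule was tested on simulated data with the 6839 regions and the depths of the 4 libraries. Planted regions were drawn only from those above a minimum mean height over the 4 libraries. Recovery in shorter regions was not simulated, so the shares recovered do not hold for all 6839 regions. Heights varied by Poisson error alone, which leaves out other variation between libraries. Of 100 regions planted 16 times higher in the high preference library, 98 were recovered, and of 100 planted 8 times higher, 40 were recovered. With the scale from estimated depth these numbers were 100 and 94. The simulated heights were drawn with the estimated depths, so that scale matched them by construction. None of 6639 unchanged regions was called for the high preference library under either scale. With the floor a call needed at least 55 reads by the planned scale and 29 by estimated depth. With Poisson error alone this left little room for a false call. Calls for the other libraries and for pairs were not simulated.

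Regions were named by a rule fixed beforehand: the 10 largest ratios in the class of the high preference library, the 5 largest in that of the low preference library, the 5 largest higher in both cocaine and in both saline libraries, and the 5 tallest by mean scaled height. Ties went to the larger height in the leading library and then to the lower coordinate. Other regions are named as chosen after their values were seen. No annotation of rn4 was used here, and the gene table at hand follows another assembly (GRCr8), so regions carry coordinates and no gene names. A planned comparison of signal at promoters and over gene lists was left out for that reason. Other settings chosen beforehand covered the length of the lists, a fixed height minimum, the overlap rule, the scale, the ratio, the bin size, the pseudocount, the hottest bins and each saline library left out in turn. Scales from estimated depth and from regions of at least 20 reads in all 4 libraries, and counts of numbered pileups, were added after seeing the data. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.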

Results

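PARP1 ChIP-seq peak lists were compared between central amygdala libraries of rats with a high preference for a cocaine-paired compartment, rats with a low preference and rats that had received only saline, all taken right after the preference test. The high and low preference groups had 1 library each and the saline group had 2, each pooled from 2 rats. There were no replicates of the cocaine groups, so differences between them have no replicate check. The lists of the high preference library, the low preference library, saline replicate 1 and saline replicate 2 held 3369978, 4037020, 793003 and 3973829 peaks on rn4. Estimated depth was 15594470, 17552845, 6618031 and 17402838 reads in the same order. Saline replicate 1 was thus the shallowest library, at 0.380 times the estimated depth of saline replicate 2. The sum of its listed heights was only 0.184 times that of saline replicate 2. Of its numbered pileups 13.8% were listed, against 32.4% in saline replicate 2.

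Most listed peaks were pileups of a few reads in every group. A height of 2 reads made up 79.1% of listed peaks in the high preference library, 76.2% in the low preference library, 90.9% in saline replicate 1 and 76.4% in saline replicate 2. Heights of at least 10 reads were reached by 680, 729, 221 and 884 peaks in that order, and heights of at least 100 reads by 25, 22, 11 and 31 peaks. The saline libraries lay 4-fold apart in their number of peaks of at least 10 reads, and both cocaine libraries fell between them. These counts are not scaled to depth. As a share of listed peaks they were 0.0202%, 0.0181%, 0.0279% and 0.0222%, with both cocaine libraries below both saline libraries. As a share of numbered pileups they were 0.00598%, 0.00591%, 0.00385% and 0.00720%, with the cocaine libraries between.

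**Figure D1:**
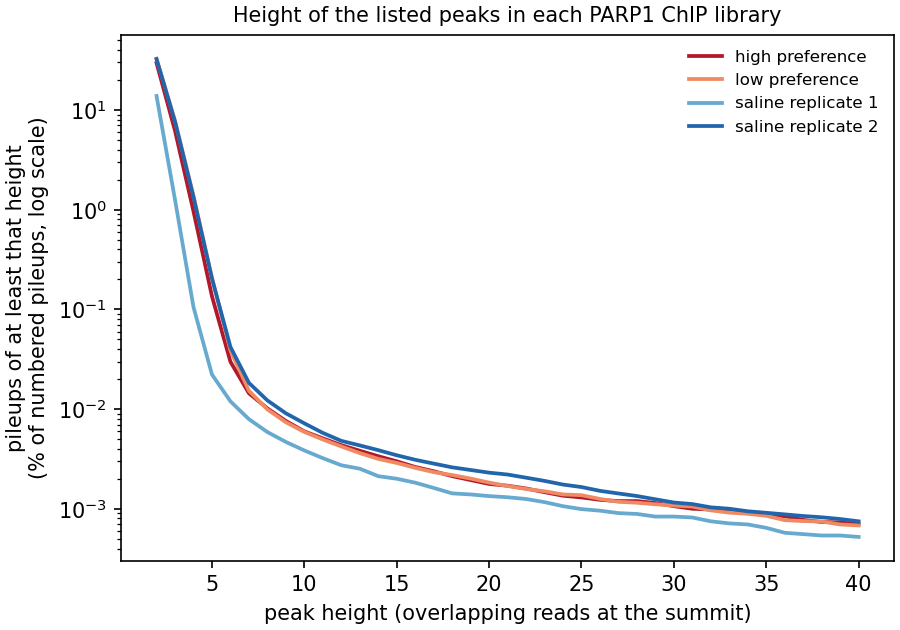
Share of numbered pileups (%, log scale) that reached each peak height (reads at the summit) in the 4 PARP1 ChIP libraries, 1 line per library. The lines of the high preference library, the low preference library and saline replicate 2 run close together, from 29.6%, 32.7% and 32.4% at a height of 2, and saline replicate 1 starts lower, at 13.8%.

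The tallest regions were shared by all 4 libraries. The tallest by mean scaled height lay on chromosome X at 22882760 to 22883741, with 670 reads in the high preference library, 695 in the low preference library, 298 in saline replicate 1 and 704 in saline replicate 2. Regions on chromosome 2 at 61089146 to 61090674 (647, 705, 287 and 766 reads) and at 156715789 to 156716687 (563, 543, 225 and 638 reads) followed. The next were on chromosome 3 at 148550988 to 148551702 (479, 483, 206 and 612 reads) and on chromosome 14 at 28434064 to 28434746 (308, 329, 133 and 333 reads). This ranking leans on saline replicate 1, which had 1231 scaled reads at the X region against 519 to 609 in the others. By estimated depth the region at 61089146 stood above the X region in low preference and saline replicate 2, and below it in the others. Ratios of unscaled heights were taken over 154 regions of at least 20 reads in the 3 deeper libraries, leaving out a region of chromosome 1 described separately. The median ratio of high to low preference was 0.996, with an SD of 0.34 on the log2 scale. The scale factors of high over low preference stood at 0.820 by the sum of listed heights and 0.888 by estimated depth, so scaling would raise this ratio. Of all 155 regions that tall, 82 (52.9%) lay in unplaced or random sequence, against 19.9% of the 6839 regions.

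Lists of the highest peaks overlapped far more than shifted lists in every pair of libraries. The list of saline replicate 1 overlapped the other saline library and both cocaine libraries at similar shares. Those lists differed in length, with 2252 peaks in saline replicate 2, 3397 in high preference and 4788 in low preference. Equal shares are therefore not equal similarity. Of 1276 highest peaks of saline replicate 1, 74.1% overlapped those of saline replicate 2 (95% Wilson interval 71.6 to 76.4). The same list overlapped the high preference library at 75.0% (72.6 to 77.3) and the low preference library at 74.9% (72.5 to 77.2), within the interval of the saline pair. These intervals treat peaks as independent, and the shares are of the same peaks, so they are no test of a difference. Without the hottest bins the shares were 62.0%, 64.6% and 62.9% for saline replicate 2, high preference and low preference. Of 2252 highest peaks of saline replicate 2, 61.5% overlapped the high preference library (59.4 to 63.4) and 63.7% the low preference library (61.7 to 65.7). Of 3397 highest peaks of the high preference library, 46.4% overlapped the low preference library (44.8 to 48.1). Shifted lists overlapped at 0.268% to 0.363% on average. Among peaks of at least 20 reads the overlap was 97.4% to 100% in the 6 pairs. The shares depended on the length of the lists. With lists of at most 20000 peaks they were 22.0% for the saline pair and 37.8% for the cocaine pair. The shorter list was then another library's, with 5157 peaks of saline replicate 2 and 4788 of low preference, whose list was unchanged. These shares are therefore not of the same lists as above.

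A single region was at least 4 times higher in the high preference library than in each of the 3 others. It lay on chromosome 1 at 162340788 to 162342127 (rn4, 1339 bp) and reached 288 reads in the high preference library (exact Poisson interval 256 to 323). Its height was 35 reads in the low preference library (24.4 to 48.7), 4 in saline replicate 1 (1.09 to 10.2) and 22 in saline replicate 2 (13.8 to 33.3). Scaled by the sum of listed heights, the high preference library stood 10.0 times above the low preference library (exact conditional binomial interval 7.05 to 14.7) and 15.7 times above saline replicate 2 (10.2 to 25.4). The ratio to the next library was 9.26 with the scale from estimated depth and 8.23 with no scaling. The next largest ratio of the high preference library was on a random part of chromosome 5 at 48989 to 49100, a region named after its values were seen, with 36 reads against 12 in low preference and none listed in saline. Its ratio by the rule, 2.64, is a lower bound against the floor of saline replicate 1, and the scaled ratio to low preference was 3.66. On simulated data 40 of 100 regions planted 8 times higher in the high preference library were recovered by this rule. With the scale from estimated depth 94 were recovered, but the simulated heights were drawn with those same depths, so a higher share was built in. That scale also called 1 region in the data. Planting was limited to regions above a minimum mean height. A single call therefore does not exclude further differences of that size, least of all in shorter regions. With the floor of saline replicate 1 a call needed at least 55 reads, which 52 of the 6839 regions had. No other region of at least 20 reads in the 3 deeper libraries differed as much between high and low preference. Unscaled ratios of the other 154 ranged from 0.449 to 1.97, against 8.23 in the chromosome 1 region. The minimum of 20 reads leaves out regions tall in high preference alone, such as the one on chromosome 5, and so narrows the range. Leaving out saline replicate 1 added a second region, on chromosome 10 at 18302557 to 18302661, with 11, 3, 0 and 2 listed reads, where 0 means not listed.

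**Figure D2:**
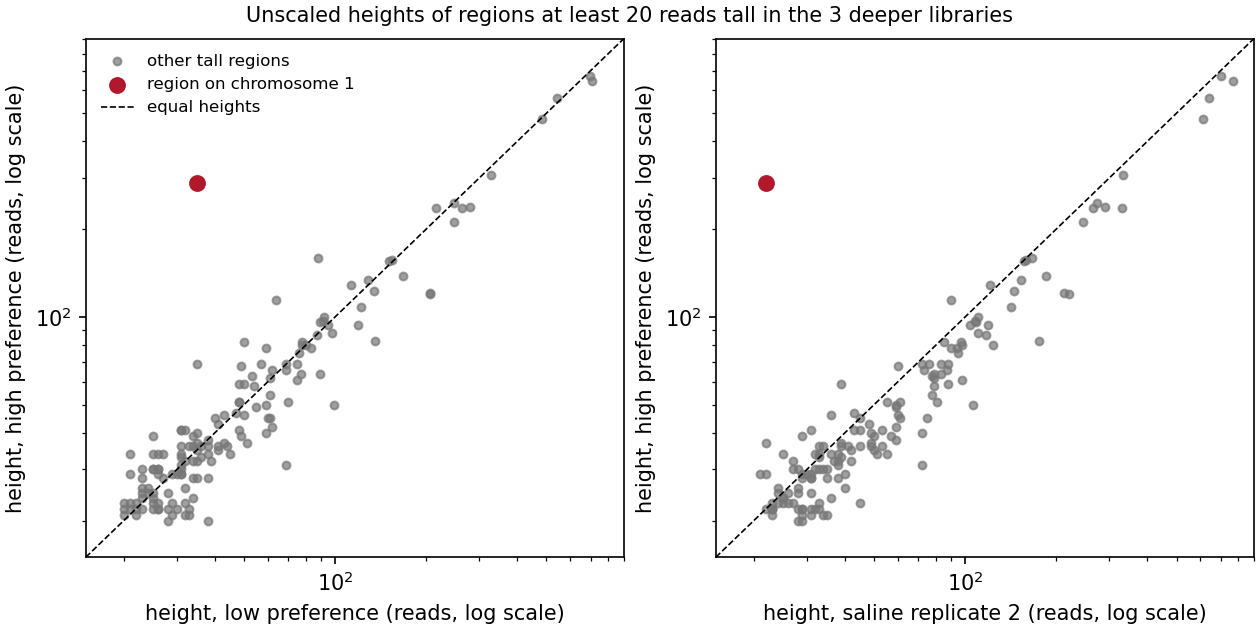
Unscaled height in the high preference library (reads, log scale) against the low preference library (left) and saline replicate 2 (right), for 155 regions of at least 20 reads in these 3 libraries, 1 point per region, with a dashed line of equal heights. The red point is the chromosome 1 region, at 288 reads against 35 and 22, and the others lie between 0.449 and 1.97 times the low preference height.

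Within the chromosome 1 region the ends of the pileup were close in the 3 deeper libraries. The single listed peak began at 162340788 in the high preference library, 162340810 in the low preference library and 162340836 in saline replicate 2. It ended at 162342127, 162342125 and 162342122 in the same order. Saline replicate 1 held 4 separate listed peaks between 162341004 and 162341697. In the 5 kb on either side no listed peak exceeded 3 reads in any library. The pileup was 1339 bp long in the high preference library, 1315 bp in the low preference library and 1286 bp in saline replicate 2.

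**Figure D3:**
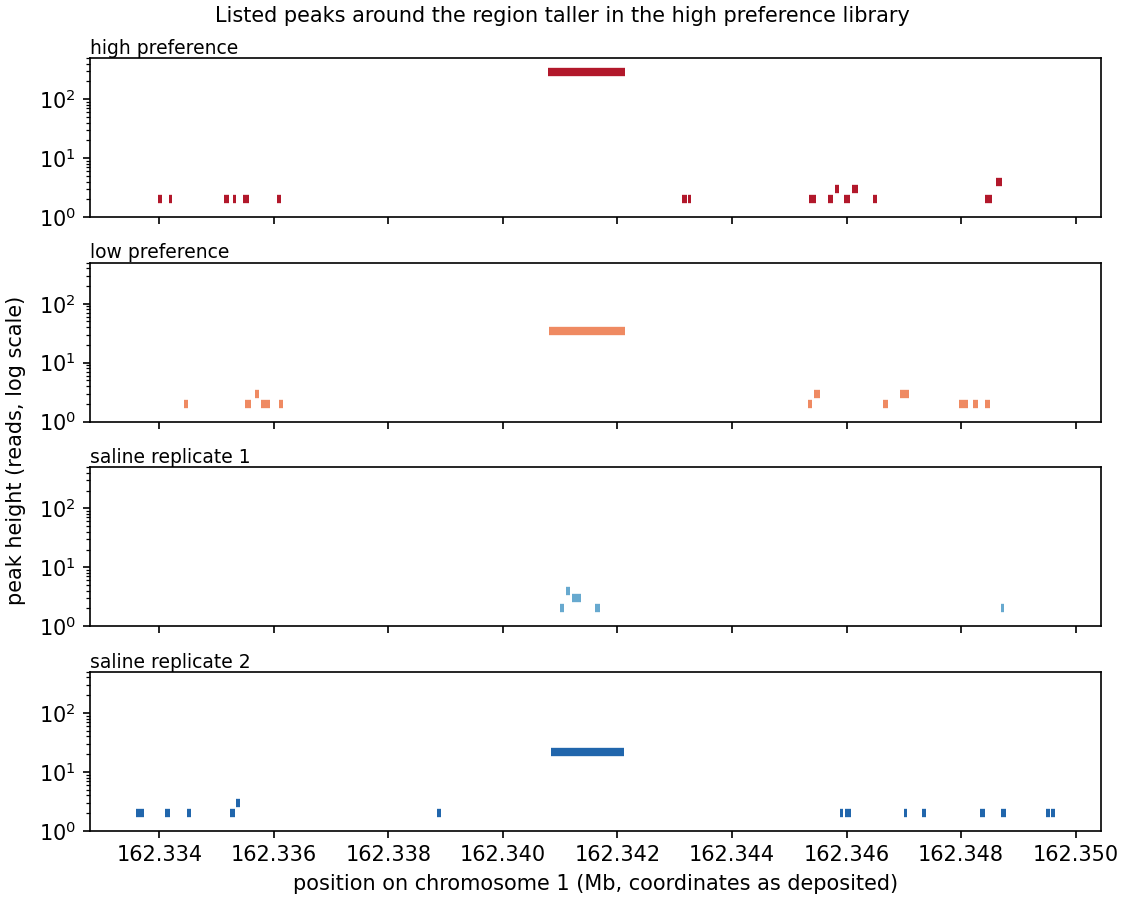
Listed peaks around the chromosome 1 region in the 4 libraries, each peak drawn as a horizontal line from its start to its end (Mb) at its height (reads, log scale). The region stands at 288 reads in the high preference library, 35 in the low preference library and 22 in saline replicate 2, and outside it no listed peak within 5 kb exceeds 3 reads.

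No region was called for the low preference library or for saline replicate 2, whose largest ratios were 1.48 and 1.59. The floor of saline replicate 1 left little room for such calls, since they needed at least 67 and 66 reads, which 42 and 56 of the 6839 regions had. Without saline replicate 1 a call needed at least 15 reads in either library, 304 and 376 regions had them, and the count was again 0 in both, with largest ratios of 2.73 and 3.30. The same rule called 277 regions for saline replicate 1, and 18 with the scale from estimated depth, under which 277 regions had a ratio of at least 2. With the others at the floor, the rule asked for at least 3 reads in saline replicate 1, which 1722 regions had, an overstated reach. With estimated depth it asked for 6 reads, which 456 had. Its count is therefore not on a par with those of the other libraries. The largest ratios among the regions of saline replicate 1, named after their values were seen, were on chromosome 15 at 92622030 to 92622264, with 7 reads against 2 in high preference, 3 in low preference and none listed in saline replicate 2, and on chromosome 18 at 35921527 to 35921592, with 34 reads against 16, 16 and 6. With the scale from estimated depth the low preference library stood highest against the others on chromosome 8 at 112352317 to 112352407, with 49 reads against 16 in high preference, 6 in saline replicate 1 and 20 in saline replicate 2, a ratio of 2.43.

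No region was at least 2 times higher in both cocaine libraries than in both saline libraries, and the largest ratio was 1.56. This count is nearly set by the floor of saline replicate 1, with which a call needed at least 28 reads in high preference and 34 in low preference, and 93 of the 6839 regions had both. In the opposite direction 44 regions were higher in both saline libraries. With the others at the floor, such a call needed 2 reads in saline replicate 1 and 8 in saline replicate 2, which 1072 regions had. Its side of the rule was thus easily met by saline replicate 1, and these calls rest mainly on saline replicate 2. The first were 2 neighbours on chromosome 12 at 3189521 to 3189615 (3, 3, 4 and 11 reads in high preference, low preference, saline replicate 1 and saline replicate 2) and at 3189616 to 3189714 (2, 2, 4 and 11 reads). Others lay on chromosome 1 at 191884112 to 191884244 (5, 6, 5 and 17 reads), on chromosome 18 at 38772680 to 38772860 (4, 5, 4 and 13 reads) and on chromosome 1 at 51093478 to 51093789 (4, 4, 3 and 12 reads). At the first of these regions the exact Poisson interval was 0.619 to 8.77 for the 3 reads of a cocaine library and 5.49 to 19.7 for the 11 reads of saline replicate 2, and the intervals overlap. Pairs that cross the groups gave from 0 to 180 regions: 180 were higher in high preference and saline replicate 1 together, 12 in low preference and saline replicate 1 together, and 0 in either cocaine library together with saline replicate 2. Only pairs with saline replicate 1 on the higher side gave any region by the planned scale, and the other pairs faced the floor of that library. In the pairs with saline replicate 1 on the higher side, that library needed only 2 reads when the others stood at the floor. These calls therefore say little about saline replicate 1. With the scale from estimated depth the counts were 155 for high preference with saline replicate 1, 45 for low preference with saline replicate 1 and 70 for the saline pair. Without saline replicate 1, 24 regions were higher in both cocaine libraries than in saline replicate 2, and 97 were higher in saline replicate 2 than in both. Under that setting 151 regions were higher in high preference and saline replicate 2 than in low preference, and 17 in low preference and saline replicate 2 than in high preference. With no scaling, 31 were higher in both cocaine libraries, against 82 in high preference with saline replicate 2 and 106 in low preference with saline replicate 2, and 1 was higher in both saline libraries. Without saline replicate 2, 2116 regions were higher in saline replicate 1 than in both cocaine libraries, with its listed heights of 2 counted as 3.

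Over 27907 bins of 100 kb the profiles of the groups were alike. Pearson's correlation across bins, which are not independent replicates, was 0.938 between high and low preference, 0.937 between high preference and saline replicate 2 and 0.959 between low preference and saline replicate 2. The pairs with saline replicate 1 were lower, at 0.891 with high preference, 0.866 with low preference and 0.865 with saline replicate 2. Spearman's correlation was 0.825, 0.771 and 0.783 in the first 3 pairs and 0.698, 0.692 and 0.648 in the others. With 100 kb bins the saline pair was therefore not closer than the pairs across groups, and the lower values went with the shallowest library. The order changed with 1 Mb bins. Low preference with saline replicate 2 was then at 0.984 and high preference with saline replicate 1 at 0.966, above 0.956 for high with low preference. The saline pair was at 0.913 and low preference with saline replicate 1 at 0.911. Bins of unplaced sequence were kept. The lowest listed height there was 2 in high preference and in saline replicate 1, and 3 in the others. With 1 Mb bins the pairs that shared this minimum had the highest correlations. How far the minimum shaped the order was not tested. With 10 kb bins the correlation fell to 0.698 for high against low preference and to 0.456 for the saline pair. With 100 kb bins and only heights of at least 3, high with low preference and low preference with saline replicate 2 were both at 0.865. High preference with saline replicate 2 was at 0.855, and the pairs with saline replicate 1 at 0.519 to 0.525.

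Signal on the X chromosome was below that on autosomes in all 4 libraries. The ratio of X to the autosome mean, per length covered by a listed peak, was 0.885 in high preference, 0.893 in low preference, 0.836 in saline replicate 1 and 0.940 in saline replicate 2. The autosomes had SDs of 0.00833, 0.0128, 0.0232 and 0.0131 in the same order, so X lay outside their spread in each library. This length is itself shorter where fewer peaks are listed, and summed heights per bp of chromosome gave ratios of 0.307, 0.310, 0.291 and 0.324. The saline libraries differed from each other by more than the cocaine libraries did. Counted as numbered pileups per Mb of chromosome, a measure added after seeing the data, the ratio was 0.564, 0.577, 0.502 and 0.592, and male rats carry a single X. With only heights of at least 3 the ratio rose above 1, to 1.09, 1.04, 1.69 and 1.13. Unplaced sequence held 1.06%, 0.433%, 1.41% and 0.521% of summed heights, and its listing minimum differed between the libraries.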

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

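The settings with a scale from estimated depth or from tall regions, and those with numbered pileups, were chosen after seeing the data, and all others were planned. Values in lists run in the order high preference, low preference, saline replicate 1 and saline replicate 2, or in the pair order high with low preference, high preference with saline replicate 1, high preference with saline replicate 2, low preference with saline replicate 1, low preference with saline replicate 2 and the saline pair. Of 160 values under another setting, 74 stayed within the limits set for each result and 86 moved. The call on chromosome 1 for the high preference library held under each of the 13 other settings run. Most of these left its ratio of 10.0 unchanged, so they put the call to little test. With another scale or no scaling the ratio was 8.23 to 10.0. The count was 2 with a ratio of at least 2, which added the region on a random part of chromosome 5 at 48989 to 49100, and 1 to 2 when a saline library was left out. The calls for low preference were 0 in each setting run, most of which keep the floor of saline replicate 1 that leaves little room for a call. Where a value moved, the cause was not tested unless stated. Listed peaks numbered 704079, 961620, 72287 and 936257 at a height of at least 3, and 680, 729, 221 and 884 at a height of at least 10, fewer by construction. The overlap was 74.7%, 85.9%, 78.0%, 83.3%, 70.8% and 85.4% with the 1000 highest peaks, and 37.8%, 26.8%, 38.5%, 23.1%, 37.0% and 22.0% with the 20000 highest. Both lengths are upper limits, and the low preference list held 4788 peaks under the limit of 20000. The shorter list, over which the share was taken, was another library's in some pairs when the limit changed. At a height of at least 10 it was 78.1%, 99.5%, 86.2%, 98.6%, 84.1% and 99.1%. Without the hottest bins it was 36.1%, 64.6%, 54.3%, 62.9%, 55.9% and 62.0%, and with an overlap of 50% of both peaks 28.4%, 32.5%, 40.8%, 30.9%, 41.6% and 26.8%. Regions called for saline replicate 1 numbered 49 with the 1000 highest peaks, 4268 with the 20000 highest, 5 at a height of at least 10, 0 with no scaling, 18 with the scale from estimated depth and 17 with that from tall regions. They numbered 1933 at a ratio of at least 2, with listed heights of 2 in that library counted as 3, and 18 at a ratio of at least 8. With an overlap of 50% of both, saline replicate 2 had 1 region and both cocaine libraries had 1. These lay on a random part of chromosome Un at 6504675 to 6506318 and on chromosome 13 at 30493017 to 30493217, and with any overlap their heights were 58, 54, 28 and 79 and 36, 41, 23 and 53 reads. Regions higher in both cocaine libraries numbered 31 with no scaling and 0 to 24 when a saline library was left out. Regions higher in both saline libraries numbered 19 with the 1000 highest peaks, 19 at a height of at least 10, 1 with no scaling (chromosome X at 147027392 to 147027524, with 3, 0, 7 and 6 reads, 0 meaning not listed), 26 with an overlap of 50% of both and 29 without the hottest bins. They numbered 70 with the scale from estimated depth, 23 with that from tall regions, 0 at a ratio of at least 4 and 97 to 2116 when a saline library was left out. The bin correlation was 0.698, 0.456, 0.686, 0.466, 0.727 and 0.456 with 10 kb bins, and 0.865, 0.525, 0.855, 0.525, 0.865 and 0.519 at a height of at least 3. With 1 Mb bins it moved to 0.966 for high preference with saline replicate 1, and with numbered pileups to 0.966 for high with low preference. The ratio of X to autosomes was 1.09, 1.04, 1.69 and 1.13 at a height of at least 3. It was 0.873 in high preference and 0.790 in saline replicate 1 without the hottest bins, and 0.564, 0.577, 0.502 and 0.592 with numbered pileups per Mb. No paired analysis was possible because the results come from no test and the groups share no pairing. The settings planned for promoters were not run, since that comparison was left out. Depth limits saline replicate 1 most, whose 793003 listed peaks were 13.8% of its numbered pileups.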

Other observations

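All tests in this part were chosen only after the results they bear on had been seen. Some unplaced regions differed between the libraries by more than the typical tall region. On chromosome Un at 53542520 to 53543001 the high preference library reached 69 reads against 35 in low preference, 23 in saline replicate 1 and 76 in saline replicate 2. At 23374231 to 23375172 it reached 31 against 69, 17 and 72. In the 100 kb of chromosome 3 from 137900000 to 138000000, saline replicate 2 had 401 numbered pileups against 197 in high preference, 225 in low preference and 87 in saline replicate 1.

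The chromosome 1 region at 162340788 to 162342127 stood at 288 reads in the high preference library against 35 in low preference, 4 in saline replicate 1 and 22 in saline replicate 2. One over-amplified library fragment is a candidate explanation that stays open, since the lists give 1 height per pileup and its length of 1339 bp was also near that in libraries without the excess. Extra copies of a stretch of DNA with fixed ends stay open too. The ends of the pileup in high and low preference differed by at most 22 bp, but 35 of 66 other tall regions had ends at least as close. PARP1 occupancy that differs with preference stays open as the biological explanation, since the high preference group had 1 library. The only input library, from the low preference group, was not analysed here. The region also lay apart between other libraries, in unscaled heights. Low preference over saline replicate 2 was 1.59, against a median of 0.870 in 154 other tall regions, 2 of them as far from it. Saline replicate 1 over saline replicate 2 was 0.182 against 0.364, with 4 as far.

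The size of the ratios in regions called for saline replicate 1 alone may owe part to a scale factor that understates its depth. In regions of at least 20 reads in all 4 libraries saline replicate 1 stood at 0.369 times saline replicate 2, and at a median of 0.364 in the 154 regions of at least 20 reads in the 3 deeper libraries, whereas the sum of listed heights gave 0.184 and estimated depth 0.380. The fall from 277 to 18 calls with the scale from estimated depth is no separate evidence, since that scale lowers nearly all ratios of this library alike, and 277 regions still had a ratio of at least 2. Why these regions stood higher was not tested, and no biological explanation was tested.

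The high preference library listed 30944 peaks on unplaced sequence against 9698 in low preference and 11309 in saline replicate 2. A lower listing minimum on that sequence may account for this, since the lowest listed height was 2 in high preference and 3 in those libraries. At a height of at least 3 the high preference library had 8523 peaks, 0.879 times the low preference number. No biological explanation was tested.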
